A study of Mus musculus with 24 samples.

How the data were processed

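RNA was measured in whole mouse ovaries that lacked or kept steroidogenic factor 1 (SF-1), the nuclear receptor encoded by Nr5a1. Knockout mice (cKO) carried 2 floxed Nr5a1 alleles and Amhr2-cre, and littermate controls carried the floxed alleles without cre. Genotype therefore goes together with carrying cre. Ovaries were collected on embryonic day 17.5 (ED17.5) and on postnatal days 1 and 4 (PND1, PND4). Per the labels, each library came from RNA pooled within an age and genotype, from 3 to 5 mice at PND1 and PND4 and from 5 at ED17.5. Poly(A) RNA was made into directional libraries. The 6 groups of age and genotype had 4 libraries each, 24 in all.

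The deposited table holds counts, as whole numbers without normalization, for 55487 Ensembl genes with their symbols. The processing notes name Trimmomatic, STAR, HTSeq and DESeq2 without versions, and the genome build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. All 24 columns were matched to samples by the library number and the title. Of the gene IDs, 99.53% were found in the GENCODE M21 annotation, which gave the coordinates. Gene-level counts of Nr5a1 take in reads from the part of the gene outside the deletion.

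Total counts per library ranged from 11361365 to 13641263, and 23428 to 24620 genes had a count. CPM (counts scaled to a common library size) were computed with library sizes scaled by trimmed mean of M-values (TMM), whose factors lay between 0.9684 and 1.017. Replicates scattered more than counting error alone gives: chi-square per degree of freedom lay between 3.164 and 21.69 over 36 pairs of replicates. Floors and intervals computed from counts cover counting error only.

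Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 17435 genes. One model of the 6 group means was fitted to all 24 libraries with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. Its contrasts were cKO against control at each age, the difference of this genotype effect between successive ages (an interaction), and successive ages within controls. P-values were adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. Values after ± are standard errors (SE) of the log2 fold change unless SD is written, and n is 4 libraries per group throughout. Each SE is the size of the log2 fold change over the square root of its quasi-likelihood F. It rests on a spread shared by all 24 libraries, not on the libraries compared alone. For shifts of gene lists, the SE comes instead from the spread of list means within the 4 libraries of each group. Nr5a1 and Amhr2 were also compared by an exact two-sided permutation test of log2 CPM (prior count 2) over the 70 assignments of 4 against 4 libraries, for which the smallest possible p is 0.0286.

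The genes to be named were set by a rule fixed before the data were examined. At each age the rule took Nr5a1, Amhr2, and the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean of at least 1 CPM over the 8 libraries and no overlap between control and cKO values. It also took up to 4 members with the smallest p of each gene list described, and 5 rises and 5 falls for each interaction and age contrast. Gene models with only a predicted name were counted but not named, and a few genes the rule takes are not reported here by name, although counts of genes and list results include them.

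The 29 gene lists were fixed before the data were examined. They cover steroidogenesis, cholesterol biosynthesis, pregranulosa cells, growing-follicle granulosa cells, theca and stroma, Sertoli cells and testis pathway, oogonia and pluripotency, meiotic prophase, germ cells of all stages, oocyte transcription factors, growing oocytes, Notch, Wnt beta-catenin, TGF-beta family and Hedgehog signalling, adhesion and basement membrane, apoptosis, cell proliferation, immediate early and stress response, endothelium, macrophages and leukocytes, erythroid cells, smooth muscle and pericytes, ovarian surface epithelium, oviduct and mesonephric duct, adrenal gland, adipocytes, skeletal muscle, and neurons and glia. Of 389 members, 388 were in the table and 369 passed the filter. Some genes stand in more than 1 list, among them Lgr5, Bmp2 and Hsd17b1. Lists were tested against all other genes with camera (limma 3.58.1, preset inter-gene correlation 0.01) and p-values were adjusted over the 87 list tests of the 3 genotype comparisons. The same test with a correlation estimated for each list was run beside it, as was fry, which asks whether the genes of a list move, on balance, one way and does not compare a list with other genes; its values are not used in the text. The age contrasts and the interactions were adjusted in the same way, each kind on its own.

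The procedure was tested on simulated data. Of 50 genes planted at each fold, 35 were called at 1.5-fold, 45 at 2-fold and 49 at 4-fold in a genotype comparison, with 5 false calls. In an interaction 18, 38 and 49 were called, with 6 false calls. An unchanged comparison gave 0 calls. Changes were planted in far fewer genes than were called in the data, and genes with the lowest mean counts were left out of the planting. The shares called therefore do not give the sensitivity of the comparisons in the data.

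The alternatives were DESeq2 size factors in the same fit, no filter on low counts, the DESeq2 1.42.0 Wald test, the 8 libraries of an age alone, the replicate number within each age as a block (for comparisons of genotype only), the library number sets as a block, leaving out each library in turn, and an estimated correlation in the list tests. Leaving out ED17.5 libraries that stood apart was added after the data were seen. Replicate numbers were not treated as pairs: residuals of 11 pairs with the same number correlated between -0.384 and 0.222 across genes, which are not independent replicates. Their mean was 0.00527, against -0.00146 for other pairs. At ED17.5, however, same-number pairs lay between 0.043 and 0.183, and 10 of all 24 libraries correlated best with their own number. A pairing is thus not excluded. No library was left out of the comparisons.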

Results

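Gene expression was measured by poly(A) RNA sequencing of whole ovaries from mice with a conditional knockout of SF-1 (cKO) and from littermate controls without cre. Ovaries were taken at 3 ages, ED17.5, PND1 and PND4, over which germ cell cysts break down and the primordial follicles that form the ovarian reserve are assembled. Each of the 6 groups had 4 libraries, each from a pool of mice. Total counts lay between 11510309 and 12919794 at ED17.5, 11668428 and 13455617 at PND1, and 11361365 and 13571755 at PND4 in controls, and between 12251798 and 13054642, 11773746 and 13641263, and 11877943 and 13328424 in cKO ovaries. The first principal component of all libraries held 56.1% of the variance and the next 14.2%.

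Nr5a1 is the floxed gene, and Amhr2 is the gene of the anti-Müllerian hormone receptor that gives the cre line its name. Nr5a1 counts include reads outside the deleted part, and the Amhr2 level goes together with carrying cre. Nr5a1 (ENSMUSG00000026751, GRCm38 chromosome 2, 38692656 to 38714542, minus strand) averaged 134.9 CPM in PND1 controls (SD 18.1, n = 4) and 68.28 CPM in cKO ovaries (SD 5.08, n = 4), 50.6% of control. At PND4 the means were 142.1 (SD 7.3) and 71.64 CPM (SD 10.3), 50.4% of control. The log2 fold change was -0.98 ± 0.23 at PND1 and -0.99 ± 0.23 at PND4, with adjusted p = 0.00301 and 0.00315, and an exact permutation test gave p = 0.0286 at each of these ages. At ED17.5 the cKO mean was 90.51 CPM (SD 49.7) against 147.3 CPM (SD 19.7), a log2 change of -0.7 ± 0.23 with adjusted p = 0.0294 and exact permutation p = 0.114. ED17.5 cKO replicate 3 held 165 CPM of Nr5a1 and the other 3 cKO libraries 62.1 to 73.1 CPM. Without that library the change was -1.17 (adjusted p = 1.4e-07). The ED17.5 call was lost without control replicate 1 (0.0602), 2 (0.0627) or 4 (0.0841) and without cKO replicate 1 (0.0831), 2 (0.103) or 4 (0.103), each an adjusted p from edgeR. Amhr2 (ENSMUSG00000023047, chromosome 15, 102445367 to 102454633, plus strand) fell to 21.4%, 21.4% and 22.6% of control at ED17.5, PND1 and PND4. Its log2 changes were -2.22, -2.23 and -2.14, each ± 0.12, with exact permutation p = 0.0286 at each age.

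**Figure D1:**
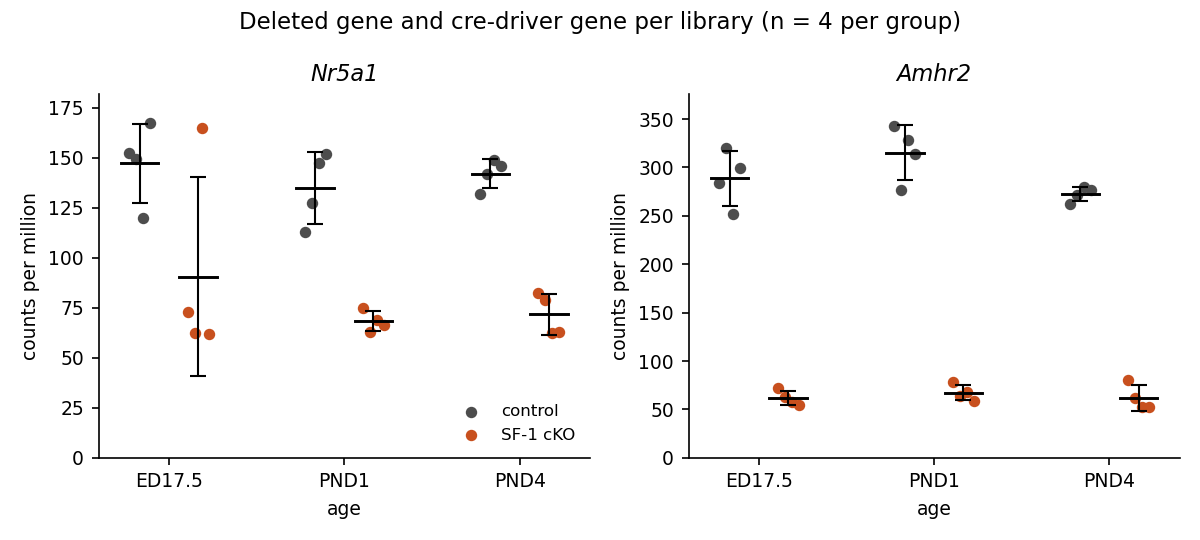
Nr5a1 and Amhr2 in CPM (vertical axis) in each library at each age, with the mean and SD of 4 libraries per group. ED17.5 cKO replicate 3 reaches 165 CPM of Nr5a1, while Amhr2 in every cKO library stays below every control library of its age.

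ED17.5 shows the fetal ovary before follicles form. Transcripts of pregranulosa cells, the supporting cells that enclose oocytes, fell, and those of theca and stroma rose. Lgr5, a receptor for R-spondins (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand), fell by 2.16 ± 0.13 on the log2 scale (adjusted p = 1.29e-10). Of 17 pregranulosa genes tested, 14 fell and 0 rose, including Irx3 (-1.79), Gng13 (-2.6) and the ligand gene Bmp2 (-1.32); the list median was -0.857 (camera adjusted p = 2.75e-20, and 0.0186 with an estimated correlation). All 13 theca and stroma genes rose, with a median of 0.894 (adjusted p = 4.72e-13, and 0.0443 with an estimated correlation), including the transcription factor gene Nr2f2 (0.89) and the receptor gene Pdgfra (1.15).

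Wnt beta-catenin signalling genes were lower at ED17.5. Of 13 tested, 7 fell and 1 rose, with a median of -0.407 (adjusted p = 6.1e-07, and 0.0325 with an estimated correlation). Rnf43, a feedback inhibitor of Wnt receptors, fell by 1.24, and the pathway targets Sp5 and Lef1 fell by 1.3 and 0.88, while the cyclin gene Ccnd1 rose by 0.58. In the Notch list 8 of 14 genes rose and 0 fell, including the receptor genes Notch1 (1.1) and Notch3 (1.01) and the coactivator gene Maml2 (0.93), with adjusted p = 2.59e-05, and 0.156 with an estimated correlation. In the TGF-beta family list 3 genes rose and 9 fell of 25, among them Bmpr1b (-1.14) and Bmp4 (1.25). Its median was -0.137, its mean 0.064 and its test downward (adjusted p = 0.00111, and 0.259 with an estimated correlation).

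Markers of vessels, macrophages and dividing cells were higher in ED17.5 cKO ovaries. Of 12 endothelial genes 7 rose, including Kdr (0.49), Tek (0.44) and Tie1 (0.72), receptors for vascular growth factors or their close relatives; adjusted p = 7.93e-06, and 0.264 with an estimated correlation. Of 13 macrophage and leukocyte genes 8 rose, including Csf1r (0.79), C1qb (0.85) and Cx3cr1 (0.86), with adjusted p = 2.59e-05, and 0.393 with an estimated correlation. Of 21 proliferation genes 14 rose and 0 fell, including Bub1 (0.45), Top2a (0.66) and Cdc20 (0.61), which act in chromosome segregation, with adjusted p = 6.1e-07, and 0.432 with an estimated correlation. Of 9 surface epithelium genes 3 fell, including the keratin genes Krt8 (-1.19) and Krt18 (-1.27), with adjusted p = 0.00763, and 0.726 with an estimated correlation; without control replicate 3 the adjusted p was 0.0816. Of 10 smooth muscle and pericyte genes 3 rose, with adjusted p = 0.0247, and 0.726 with an estimated correlation; without control replicate 2 or cKO replicate 2 it was 0.0605 or 0.0533. Bcl2l11, which encodes a pro-apoptotic protein, rose by 0.86 ± 0.08 among 20 apoptosis genes, of which 5 rose and 2 fell (list adjusted p = 0.344). Hedgehog genes rose in 4 of 12 (0.097), adhesion and basement membrane genes gave 4 rises and 3 falls of 15 (0.879), and 2 of 11 immediate early genes rose (0.0897). Without cKO replicate 3, 2 Hedgehog genes rose and 1 fell (median -0.02, camera adjusted p = 0.562).

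Testis and steroidogenic transcripts at ED17.5 moved with a single library. Of 11 Sertoli and testis pathway genes 5 rose, with a list median of 1.228 (adjusted p = 0.0193, and 0.726 with an estimated correlation). Ptgds, a prostaglandin D synthase gene, rose by 1.88 and Cyp26b1, whose enzyme degrades retinoic acid, by 1.74; without cKO replicate 3 they still rose by 1.37 and 1.34. Without that library Gdnf changed from 2.77 to 0.74 (adjusted p = 0.364), Dmrt1 from 1.7 to 0.32 (0.56), Cst9 from 3.27 to -1.65 (0.00342), and the list median fell to 0.185 (0.775), with 2 members higher and 3 lower. Cst9 is named after its values were seen. The same library held 324 CPM of Amh, the gene of anti-Müllerian hormone, against 0.319 to 1.46 CPM in the other 7 ED17.5 libraries, and Amh changed from 6.35 to -0.14 without it (adjusted p = 0.944). Of 16 steroidogenesis genes 2 rose and 2 fell, and camera read the list as lower (adjusted p = 0.928) although its median was 0.144. Without cKO replicate 3, 8 steroidogenesis genes fell and 0 rose, with a median of -0.575 (adjusted p = 1.25e-05, and 0.06 with an estimated correlation). Cyp17a1 and Cyp11a1, which encode enzymes of androgen and pregnenolone synthesis, then changed from 5.37 to -1.84 (adjusted p = 7.26e-05) and from 4.69 to -0.76 (0.166). In the cholesterol biosynthesis list 1 of 20 genes fell, with a median of 0.041 and a downward test (adjusted p = 0.879); without this library 5 fell (median -0.193, 0.000941, and 0.436 with an estimated correlation). Growing-follicle granulosa genes gave 3 rises and 2 falls of 13, with a median of 0.135 and a downward test (adjusted p = 0.879; -0.848 and 0.0943 without the library). Among them Nr0b1, which encodes the nuclear receptor DAX1, fell by 1.57 and Inhba, an activin subunit gene, rose by 1.82 with and by 1.04 without it.

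**Figure D2:**
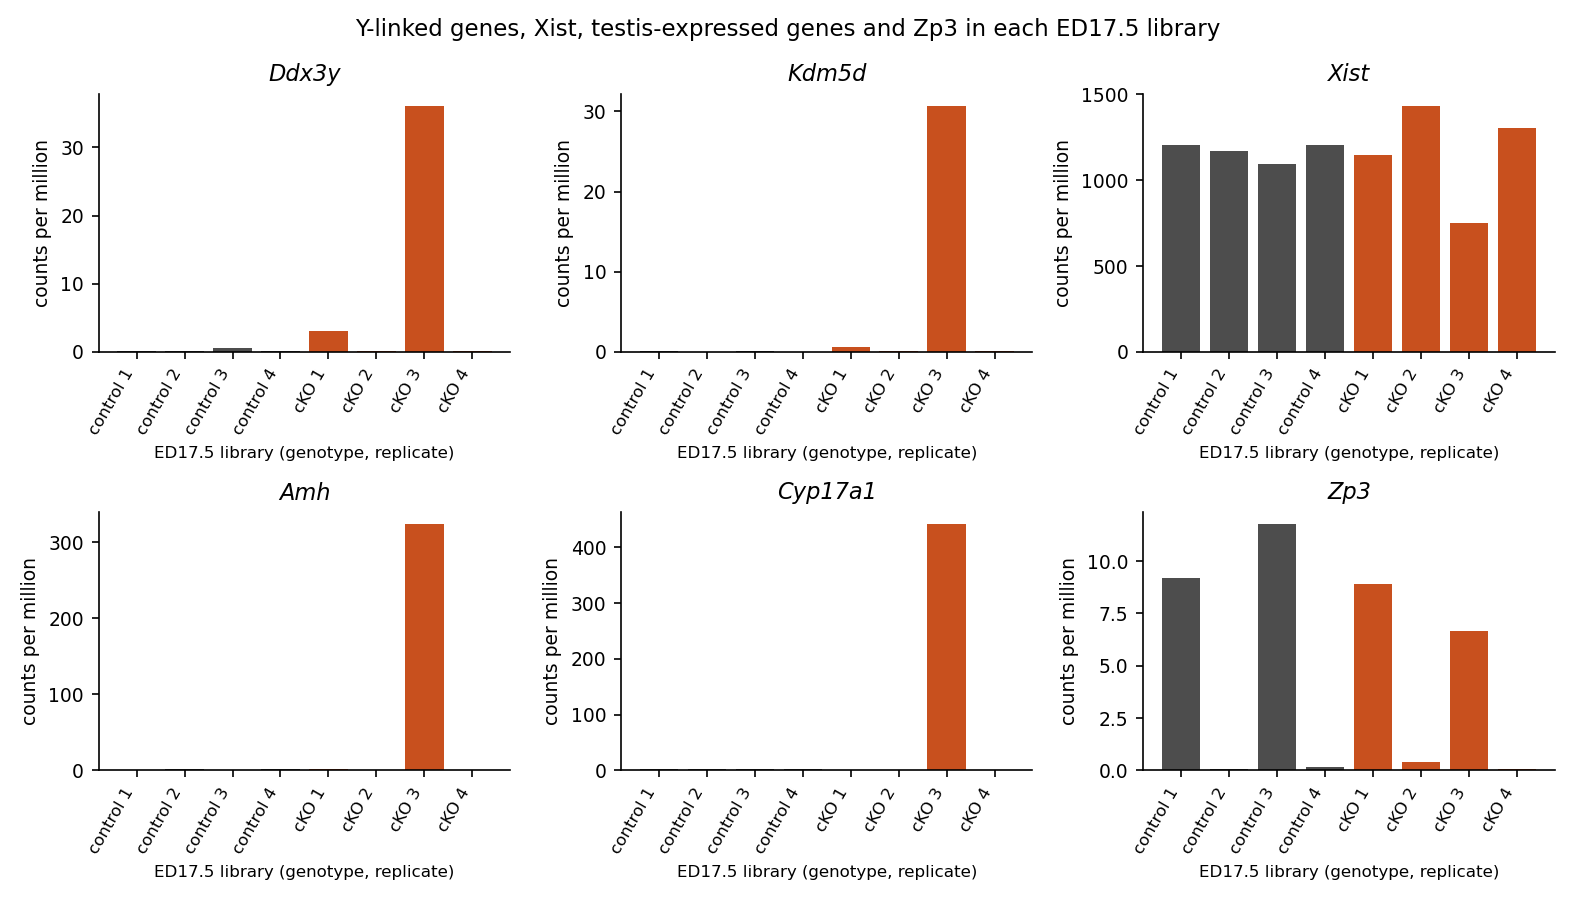
CPM (vertical axes from 0) of 2 Y-linked genes, Xist, Amh, Cyp17a1 and Zp3 in each of the 8 ED17.5 libraries. ED17.5 cKO replicate 3 alone reaches 324 for Amh and 441 for Cyp17a1 and has the lowest Xist, 753.

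Germ cell lists at ED17.5 held genes that moved both ways. In the list of germ cell genes of all stages 1 of 12 fell, with a median of -0.225 (adjusted p = 0.522). Of 29 meiotic prophase genes 7 rose and 1 fell (median 0.227, adjusted p = 0.0374, and 0.958 with an estimated correlation), including Rec8, a meiotic cohesin gene (-0.85), and Msh5 (0.7) and Dmc1 (0.66), which act in meiotic recombination. The list call was lost without control replicate 1 (adjusted p = 0.145) or 3 (0.224) and without cKO replicate 1 (0.132), 2 (0.0533) or 4 (0.0789). Of 11 oogonia and pluripotency genes 1 rose and 1 fell (0.685). Of 8 oocyte transcription factors 1 rose and 3 fell (list adjusted p = 0.279), among them Nobox, which acts in early follicles, at -1.03 (adjusted p = 0.0124, and 0.05 without control replicate 3). Without cKO replicate 3, 1 of these 8 rose and 1 fell (median -0.55). Of 21 growing oocyte genes only Tle6, a maternal-effect gene, passed (-0.9 ± 0.17; list adjusted p = 0.367). ED17.5 libraries differed in these transcripts within both genotypes: Zp3, a zona pellucida gene, averaged 9.13 CPM in the 4 libraries numbered 13 to 24 and 0.179 CPM in the 4 numbered 1 to 12. The calls of Msh5 and Dmc1 were lost without those 4 libraries, with adjusted p = 0.104 and 0.116.

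Across all genes at ED17.5, 4040 of 17435 passed the threshold in edgeR, 1941 higher and 2099 lower, and 716 of them by at least 2-fold; with DESeq2 size factors 2060 were higher and 1968 lower. The largest rises by the rule were in Cbln4 (4.32 ± 0.85), a cerebellin gene, Gdnf, Sostdc1 (2.23) and Enpp6 (2.23 ± 0.33), and reached down to Tmem132b (1.86) and Crct1 (1.94). Without cKO replicate 3, Cbln4 was at 2.51, Sostdc1 at 1.25, Mafa at 1.06 instead of 2.18, Pdlim3 at 1.09 instead of 2 and Adamtsl2 at 1.6 instead of 1.9, all still called; Dusp15 changed from 2.19 to 0.83 (adjusted p = 0.0715) and Cadps from 2.05 to 0.59 (0.232). The largest falls were in Oprk1, which encodes the kappa opioid receptor (-3.14 ± 0.27), Srd5a2, a steroid 5-alpha reductase gene (-3.13 ± 0.31), Svs5 (-2.95) and Tmc1 (-2.85). They went on with Slc6a7 (-2.85), Slc5a4a (-2.83), Cyp2f2 (-2.62), Gng13, Trim66 (-2.58), Kcnip4 (-2.56), Nmur2 (-2.42) and Insyn2b (-2.39). Control and cKO values did not overlap in 23.8% of the genes, against 2.86% by chance. Without cKO replicate 3, 3650 genes were called, and 3290 without the 4 libraries numbered 13 to 24.

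At PND1, when most germ cells are passing from cysts into follicles, the supporting and stromal differences seen before birth were present again. Lgr5 fell by 2.36 ± 0.13 (adjusted p = 1.47e-11), and 11 of 17 pregranulosa genes fell and 0 rose, including Gng13 (-3.18), Irx3 (-1.6) and Irx5 (-1.04). The list median was -0.583 (adjusted p = 1.46e-12, and 0.0443 with an estimated correlation). All 13 theca and stroma genes rose (median 1.252, adjusted p = 3.39e-21, and 0.0186 with an estimated correlation), among them the receptor gene Pdgfrb (1.82), the collagen gene Col3a1 (1.28) and Maf (1.08). All 12 endothelial genes rose, including Tek (0.81), Pecam1 (0.91) and Kdr (0.68), with a median of 0.847 (adjusted p = 5.28e-13, and 0.0443 with an estimated correlation). Of 13 macrophage genes 9 rose, including the complement genes C1qb (1.71) and C1qa (1.3) and the receptor gene Csf1r (1.39); adjusted p = 9.06e-12, and 0.065 with an estimated correlation.

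Signalling lists at PND1 moved as follows. Of 13 Wnt genes 8 fell and 2 rose (median -0.454, adjusted p = 6.7e-06, and 0.0443 with an estimated correlation), including Rnf43 (-1.35), Axin2 (-0.7) and Sp5 (-1.1). Of 14 Notch genes 8 rose, including Notch3 (1.59) and Maml2 (0.9), and 1 fell, the target gene Hes1 (-0.63); adjusted p = 0.00656, and 0.445 with an estimated correlation. Of 12 Hedgehog genes 7 rose and 1 fell, including Gas1 (0.99), a co-receptor gene, and the effector gene Gli2 (1.5), with adjusted p = 0.00247, and 0.393 with an estimated correlation. The TGF-beta family list had 4 rises and 6 falls of 25 (adjusted p = 0.502), with Id3, a target of BMP signalling, at 0.64 and Bmp4 at 1.36. Of 10 smooth muscle and pericyte genes 7 rose, among them Mylk (0.78) and Rgs5 (1.07), with adjusted p = 0.000206, and 0.426 with an estimated correlation. Surface epithelium genes moved both ways: Krt8 (-1.25) and Krt18 (-1.44) were among 3 that fell and Lrrn4 (1.49) was 1 of 2 that rose (list adjusted p = 0.0193, and 0.726 with an estimated correlation). In the adhesion and basement membrane list 8 rose and 2 fell of 15 (adjusted p = 0.0897).

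At PND1 few genes of steroidogenesis and of germ cells passed. The spread of each gene was estimated over all 24 libraries. ED17.5 cKO replicate 3, with 441 CPM of Cyp17a1 and 324 CPM of Amh, thus enters it. Steroidogenic, Sertoli and granulosa genes that did not pass were not shown to be unchanged. Of 16 steroidogenesis genes 1 fell, Fdxr (-1.18), which encodes ferredoxin reductase (list adjusted p = 0.421). In cholesterol biosynthesis 5 of 20 fell, including Hmgcs1 (-0.79), with adjusted p = 0.00729, and 0.817 with an estimated correlation. Nr0b1 fell by 1.93 and Nr5a2 rose by 0.56, while the other 11 growing-follicle granulosa genes did not pass (adjusted p = 0.722). In the Sertoli list 2 rose and 1 fell, Cyp26b1 at 1.7 and Mro at -1.62 (adjusted p = 0.729). Of the 12 germ cell genes of all stages 1 fell (adjusted p = 0.421), of 29 meiotic genes 2 fell, Rec8 by 0.97 (list adjusted p = 0.388), and 0 of 21 growing oocyte genes, 0 of 8 oocyte transcription factors and 0 of 11 oogonia genes passed (adjusted p = 0.621, 0.522 and 0.685). The pro-apoptotic genes Bcl2l11 (1.1) and Bmf (1.12) rose, with 4 rises and 2 falls among 20 apoptosis genes (adjusted p = 0.263). Immediate early genes rose in 3 of 11 (adjusted p = 0.0247, and 0.726 with an estimated correlation), and 0 of 21 proliferation genes passed (0.969).

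Across all genes at PND1, 4176 passed in edgeR, 2304 higher and 1872 lower, and 1090 by at least 2-fold; with no filter 1853 were higher and 1988 lower. Egfem1 (3.62 ± 0.52), Angptl7, an angiopoietin-like gene (3.32 ± 0.26), Nwd2 (3.24) and Asic1, an acid-sensing ion channel gene (3.14), rose most. They were followed by Lgr6 (3.06), Grik1 (2.97), Corin (2.83), Enpp6 (2.8), Diras2 (2.65), Asic4 (2.61), Hpca (2.6) and Lamc3 (2.51). Oprk1 fell most, by 4.66 ± 0.42, from 3.32 to 0.121 CPM, followed by Rhox8 (-3.57), a member of a multigene family, Insyn2b (-3.35) and Gng13. The other large falls were in Cst8 (-3.03), Tmem130 (-2.98), Rasal1 (-2.73), Sowaha (-2.71), Ct55 (-2.6), Acsbg1 (-2.52), Pdzd7 (-2.49) and Tmprss13 (-2.5), whose adjusted p of 0.0191 became 0.0531 without cKO replicate 3. Values of the genotypes did not overlap in 27.7% of genes, against 2.86% by chance.

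At PND4, with primordial follicles formed and the first follicles growing, the same groups stood apart by genotype. Lgr5 fell by 2.62 ± 0.13 (adjusted p = 2.5e-12), from 116 to 18.9 CPM, and Irx3 (-2.34), Gng13 (-3.3) and Irx5 (-1.84) were among 12 of 17 pregranulosa genes that fell, with 0 that rose (median -0.466, adjusted p = 1.35e-16, and 0.0305 with an estimated correlation). Of 13 theca and stroma genes 10 rose, including Pdgfrb (1.5) and Col3a1 (1.06), with a median of 0.985 (adjusted p = 3.71e-11, and 0.065 with an estimated correlation). All 12 endothelial genes rose, among them Pecam1 (1.06), Tek (0.78) and Tie1 (1.14), with a median of 0.971 (adjusted p = 2.4e-15, and 0.0305 with an estimated correlation). All 13 macrophage genes rose, among them Csf1r (1.03), C1qa (1.12) and C1qc (1.13), with adjusted p = 3e-10, and 0.103 with an estimated correlation.

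The Wnt list had 7 falls and 0 rises of 13 at PND4 (median -0.554, adjusted p = 8.11e-11, and 0.0186 with an estimated correlation), including Rnf43 (-1.6), Axin2 (-1.1) and Lef1 (-1.27). Hes1 fell by 0.81 and Notch3 rose by 1.42 in the Notch list, where 6 rose and 1 fell (adjusted p = 0.0995). Gas1 (0.78) was 1 of 6 Hedgehog genes that rose, with 0 that fell (adjusted p = 0.0226, and 0.586 with an estimated correlation); without cKO replicate 1 the adjusted p was 0.0839. In the TGF-beta family list 6 rose and 3 fell, Id3 by 1.07 upward; the median was -0.107 and the test upward (adjusted p = 0.969). Krt8 (-1.61) and Krt18 (-1.86) were among 5 surface epithelium genes that fell, and Lrrn4 (1.58) was 1 of 2 that rose (adjusted p = 3.48e-05, and 0.424 with an estimated correlation). Rgs5 (1.19) and Mylk (0.52) were among 5 smooth muscle and pericyte genes that rose (adjusted p = 0.00208, and 0.567 with an estimated correlation).

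Germ cell lists at PND4 had few changed members: 1 of 12 genes of all stages fell, 1 of 29 meiotic genes rose, Dmc1 (0.65), and 1 fell, Rec8 (-1.24), and 0 of 21 growing oocyte, 0 of 8 oocyte transcription factor and 0 of 11 oogonia genes passed. The adjusted p of these 5 lists were 0.421, 0.558, 0.621, 0.722 and 0.522. Of 16 steroidogenesis genes 0 passed (0.344), and 2 of 20 cholesterol genes fell (list adjusted p = 0.0897). As at PND1, ED17.5 cKO replicate 3 entered the spread used here, so genes that did not pass were not shown to be unchanged. Nr0b1 (-2.03) was 1 of 2 growing-follicle granulosa genes that fell and 1 of 13 rose (0.337). In the Sertoli list Cyp26b1 rose (1.16) and Mro fell (-1.97), with list adjusted p = 0.969. The death receptor gene Fas (1.16) and Bmf (1.06) were among 4 apoptosis genes that rose, and 1 fell (0.307). In the adhesion list 4 rose and 4 fell (0.453), and 0 of 21 proliferation and 0 of 11 immediate early genes passed (0.399 and 0.683).

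Across all genes at PND4, 3999 passed in edgeR, 2195 higher and 1804 lower, and 1023 by at least 2-fold; with DESeq2 size factors 2015 were higher and 2115 lower, and with no filter 1678 and 1873. The largest rises were in Egfem1 (3.91 ± 0.59), Angptl7 (3.87 ± 0.28), Car10 (3.23), Ifi204 (3.1), Grik1 (2.95), Mcemp1 (2.91), Corin (2.89), Gbp2b (2.75), Serpina3n (2.74), Asic1 (2.74), Pirb (2.69) and Dscaml1 (2.65). Ifi204, Gbp2b and Pirb belong to multigene families whose members can share reads. The call of Mcemp1 (adjusted p = 0.0257) was lost without control replicate 3 (0.053), 4 (0.0664) or 5 (0.0687) or cKO replicate 3 (0.0507) or 4 (0.0721). The largest falls were in Gpr55, a receptor for lysolipids (-3.86 ± 0.31), Rdh1, a retinol dehydrogenase gene (-3.83 ± 0.45), Ct55 (-3.42), Gng13, Rarres1 (-3.18), Celf3 (-3.14), Insyn2b (-3.13), Acsbg1 (-2.86), Rhox8 (-2.83), Sectm1b (-2.7), Cst8 (-2.63) and Lgr5. Values of the genotypes did not overlap in 24% of genes, against 2.86% by chance.

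**Figure D3:**
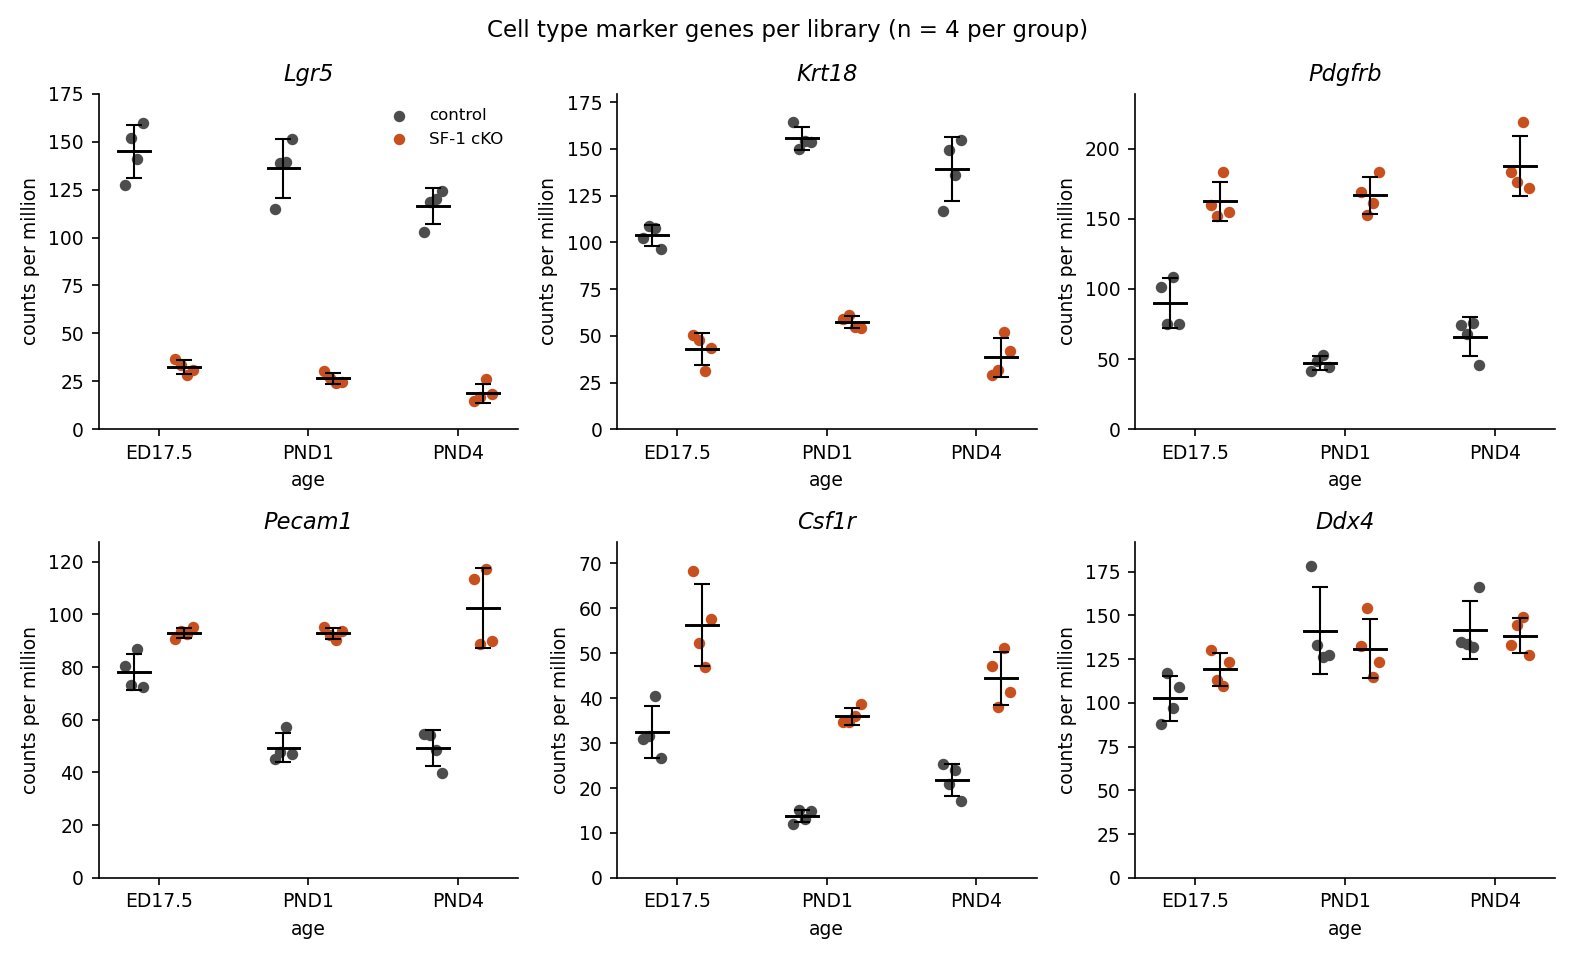
CPM (vertical axes from 0) of Lgr5, Krt18, Pdgfrb, Pecam1, Csf1r and Ddx4 in each library at each age, with the mean and SD of 4 libraries per group. Lgr5 averages 116 in PND4 controls and 18.9 in PND4 cKO ovaries, while control and cKO values of Ddx4, a germ cell gene, overlap at each age.

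**Figure D4:**
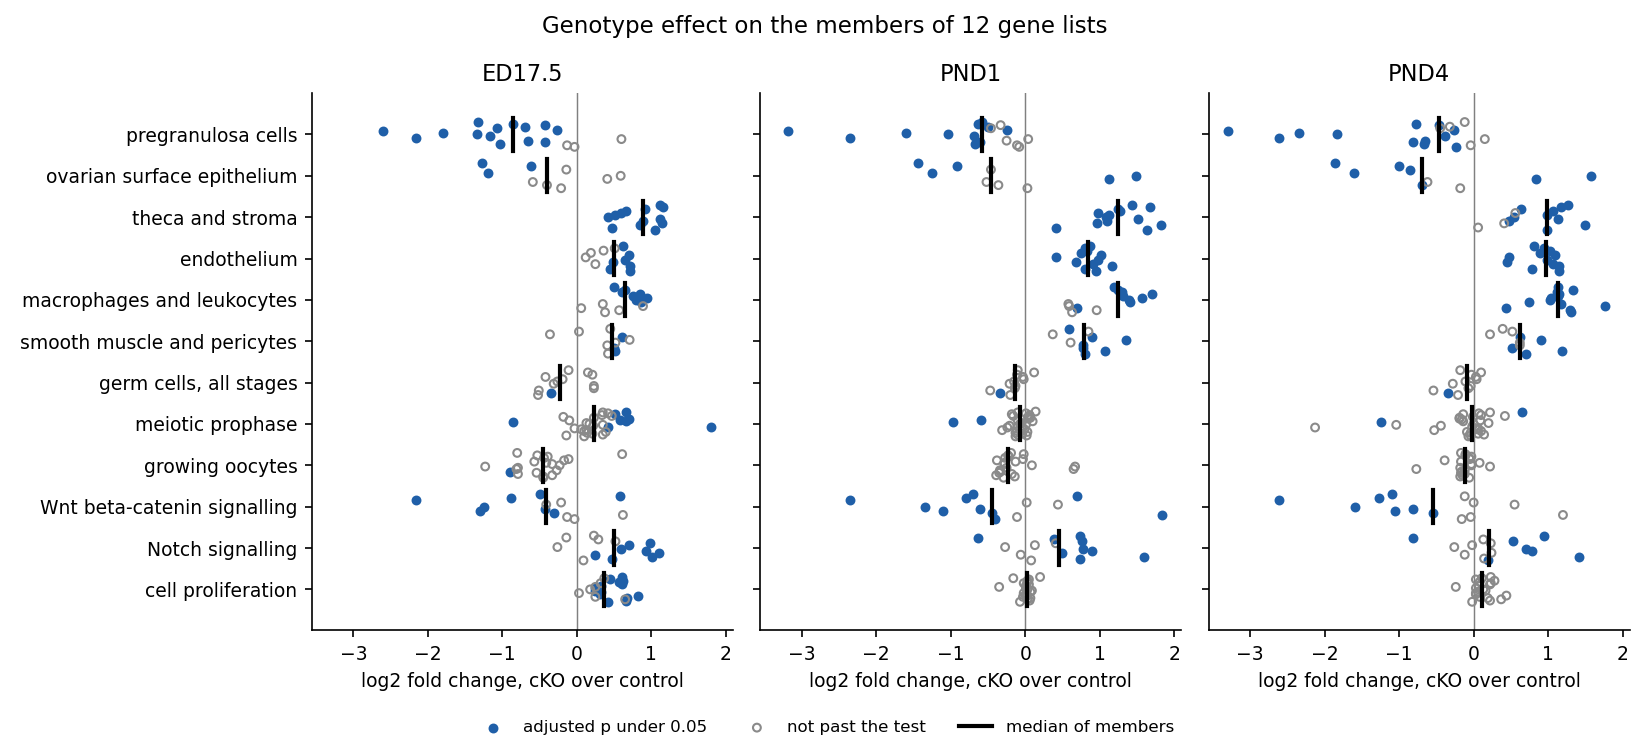
Log2 fold change, cKO over control (horizontal axis), of the tested members of 12 gene lists at each age, filled where the adjusted p of the gene passes 0.05, with a line at the list median. At PND1 the pregranulosa median lies at -0.583, the theca and stroma median at 1.252 and the median of germ cells of all stages at -0.132.

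The lists of tissues next to the ovary and of erythroid cells did not pass the test at any age, which does not show that they were unchanged. Their ED17.5 medians ran from -0.042 for the adrenal gland to 0.534 for erythroid cells and 0.858 for adipocytes (-0.93 without cKO replicate 3). Of 9 erythroid genes 0 passed at each age (adjusted p = 0.685, 0.367 and 0.263). Of 9 oviduct and mesonephric duct genes 1 fell at each age and 1 rose at PND1 and at PND4 (0.453, 0.886 and 0.685), and of 6 adrenal genes 1 fell, at PND1 (0.969, 0.685 and 0.969). Of 3 adipocyte genes 1 fell at ED17.5 (0.879, 0.969 and 0.879), of 8 skeletal muscle genes 1 fell at each age and 1 rose at PND1 (0.886, 0.729 and 0.257), and of 6 neuron and glia genes 1 rose and 1 fell at each age (0.879, 0.832 and 0.771). Adjusted over the list alone, the ED17.5 counts were 10 rises of 12 for endothelium, 10 of 14 for Notch, 17 of 21 for proliferation, and 14 falls and 1 rise of 17 for pregranulosa cells. At PND1 and PND4 they were 13 falls of 17 for pregranulosa cells each, 12 and 13 rises of 13 for macrophages, and 13 and 12 of 13 for theca and stroma, adjusted over the list alone. The list calls that held with an estimated correlation were pregranulosa cells and Wnt signalling at each age, theca and stroma at ED17.5 (but 0.06 without cKO replicate 3) and PND1, and endothelium at PND1 and PND4.

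Genotype effects at the 3 ages overlapped. Higher at all ages were 971 genes and lower at all ages 808, where independent lists would share 32.29 and 23.32. Opposite calls numbered 93 over the pairs of ages, with a gene counted once for each pair in which its calls were opposite. Tests of the difference itself found 325 genes whose genotype effect differed between ED17.5 and PND1, 209 with a more positive effect at PND1, and 18 between PND1 and PND4, 6 with a more positive effect at PND4. Theca and stroma genes were among the former: Pdgfrb (0.98 ± 0.19), Maf (0.66 ± 0.14) and Col3a1 (0.63 ± 0.16) had a more positive effect at PND1, as did the endothelial gene Pecam1 (0.66 ± 0.14), the kainate receptor gene Grik1 (2.64 ± 0.45) and Chodl (2.62 ± 0.34, from -1.8 at ED17.5 to 0.82 at PND1). Id3 differed in both steps, by 0.88 ± 0.08 and by 0.43 ± 0.08. With 1 library left out, 13 of 16 settings ended the call of Col3a1 at the earlier step and 10 of 16 that of Id3 at the later step. Mpo, Ctsg and Prtn3, proteins of granulocyte precursors, gave 8.53, 8 and 4.83, with Mpo between 3.74 and 174 CPM within ED17.5 controls alone. Rasl10a (-3.02), Gfap (-2.46), Rasal1 (-1.78) and Rarres1 (-1.67) were among the most negative at the earlier step. At the later step Oprk1 (3.86, with control and cKO ovaries both at a few counts at PND4, 0.435 and 0.243 CPM, after 3.32 CPM in PND1 controls), Trim66 (1.65), Astn1 (1.16), Thbs2 (0.95) and Bace2 (0.9) were the most positive, and Grhl3 (-1.77), Pitpnm3 (-1.68), Tnni1 (-1.39), Sntb1 (-1.07) and Plekha6 (-1.03) the most negative; the cyclin gene Ccnd1 gave -0.82. The earlier count was 216 without ED17.5 control replicate 3, 196 without ED17.5 cKO replicate 4, 530 without ED17.5 cKO replicate 1, 216 and 205 without PND1 control replicates 1 and 2, and 157 without PND1 cKO replicate 3. With DESeq2 it was 608. Which direction held more genes depended on the libraries: without the 4 ED17.5 libraries numbered 13 to 24, 121 were more positive and 313 more negative at PND1, and without ED17.5 cKO replicates 1 and 3, which hold the most Y-linked reads (78 and 1415 counts), 315 and 343 (658 in all), a setting that leaves cKO libraries numbered 1 to 12 alone against controls of both number sets. The later count was 64 with DESeq2 and 64 with a replicate block, 11 without PND1 control replicate 3, 10 without PND1 cKO replicate 4 and 49 without PND4 control replicate 5. The replicate block leaves PND4 control replicate 5 and PND4 cKO replicate 1 without a partner.

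In control ovaries, genes of growing oocytes rose with age and most genes of meiotic prophase fell. From ED17.5 to PND1, 20 of 21 growing oocyte genes rose, including Tle6 (1.99 ± 0.16) and Uchl1 (3.26 ± 0.28), and 7 of 8 oocyte transcription factors, including Tbpl2 (4.57) and Sohlh1 (2.82), with camera adjusted p = 4.59e-09 and 4.41e-06, and 0.533 and 0.409 with an estimated correlation. Of 29 meiotic prophase genes 19 fell, including Spo11 (-3.14), which makes the breaks that start recombination, and Meioc (-3.68), and 4 rose (adjusted p = 2.98e-06, and 0.568 with an estimated correlation). Of 11 oogonia and pluripotency genes 8 rose, with Lin28a at 3.75 and Kit at 2.52 (adjusted p = 4.6e-05, and 0.409 with an estimated correlation). All 13 theca and stroma genes fell, including Maf (-1.05) and Wnt5a (-1.86), and 9 of 13 macrophage genes fell, including Csf1r (-1.24); adjusted p = 1.54e-05 and 0.000113, and 0.533 and 0.551 with an estimated correlation. From PND1 to PND4, 18 of 21 growing oocyte genes rose further, including Bcl2l10 (2.96) and Gdf9 (2.75), a growth factor gene of oocytes, while 19 of 29 meiotic genes fell, including Syce3 (-2.87) and Stag3 (-1.57), with adjusted p = 2.03e-12 and 7.96e-10, and 0.533 each with an estimated correlation. All 10 smooth muscle and pericyte genes rose, including Myh11 (2.41) and Mylk (0.79), and 7 of 13 growing-follicle granulosa genes, including Esr2 (1.66) and Nr5a2 (1.16), with adjusted p = 7.45e-11 and 0.00108, and 0.409 and 0.587 with an estimated correlation.

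Across all genes, 9246 changed from ED17.5 to PND1 in controls, 4421 higher and 4825 lower, and 5565 from PND1 to PND4, 2839 higher and 2726 lower. With no filter the earlier step gave 4699 higher and 4240 lower, and without the 4 ED17.5 libraries numbered 13 to 24 it gave 4172 and 3721. Several of the largest changes ran to or from a few counts, and are given as mean CPM. Tmco5b went from 0.0384 to 3.51, Iqcf5 from 0.0406 to 2.97, Krt83 from 0.0386 to 2.35, Ms4a1 from 0.0581 to 2.44 and C86187 from 0.174 to 6.47. Serpind1, a gene of the liver, went from 4.11 CPM to 0 counts in all 4 PND1 controls, at least 67.7-fold lower against a floor of 3 counts over the group, and Uroc1 from 2.34 CPM to 0 counts, at least 38.6-fold lower. Serpina6 went from 11.6 to 0.0555 and Serpina1c, a member of a multigene family, from 4.42 to 0.0185. Alb and Afp, abundant liver transcripts chosen after the values were seen, averaged 598 and 360 CPM in ED17.5 controls and 8.11 and 4.2 CPM in PND1 controls. From PND1 to PND4 the oocyte genes Obox5 (0.0205 to 3.92), Oosp1 (0.402 to 25.9), Nlrp2 (0.214 to 9.23), Nlrp9a (0.229 to 7.51) and Zar1l (0.124 to 4.18) rose most, several of them with close paralogs. Sp9 (3.24 to 0.138), Taf7l (99.4 to 5.64), Ctag2l1 (12.2 to 0.726), Tex101 (13.7 to 0.838) and Adad1 (3.11 to 0.209) fell most.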

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

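The tests of the ED17.5 cKO replicate 3 pattern below were chosen after its values had been seen; the tests of differences between ages and of other splits were planned, except that the look at splits with equal exchanges was added later.

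ED17.5 cKO replicate 3 held transcripts of the fetal testis that the other 7 ED17.5 libraries held at lower levels: 324 CPM of Amh, 441 of Cyp17a1, 55.3 of Insl3 and 40 of Sox9, the last 2 chosen after the values were seen. It also held 112 CPM (1415 counts) of 4 Y-linked genes, 17.7 times the next library, ED17.5 cKO replicate 1 with 6.32 CPM, and the lowest Xist at ED17.5, 753 CPM, so that RNA of a male gonad in this pool is a candidate explanation. Testis genes turned on by loss of SF-1 would have to be higher in the other cKO libraries as well, and over the 66 genes at least 4-fold above every control in this library the other 3 differed from controls by a median of -0.01 log2, with quartiles of -0.46 and 0.63 that leave this open for part of the genes. A control library with the wrong label would have Amhr2 at the level of controls, and Amhr2 here was 23% of the lowest control. Whether a share of male tissue also accounts for the 165 CPM of Nr5a1 in this library stays open.

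Within groups of 4 libraries, 35 of 501 gene-by-group values had a library farther from the other 3 than Dixon's 95% critical value (6.99%; chance gives about 1 in 20 groups). ED17.5 cKO replicate 3 gave 14 of them, with the gap to the nearest library over the whole range at 0.991 for Cyp17a1, 0.988 for Bmp4, 0.969 for Cst9, 0.923 for Inhba, 0.91 for Cyp26b1, 0.904 for Adamtsl2, 0.893 for Notch3, 0.875 for Sostdc1, 0.868 for Fdxr, 0.866 for Gdnf, 0.865 for Ptgds, 0.856 for Pdlim3, 0.834 for Cadps and 0.832 for Nr5a1. In ED17.5 controls the ratio was 0.915 for Nid2, 0.853 for C1qb and 0.842 for Oprk1 in replicate 3, 0.845 for Tie1 in replicate 2, and 0.863 for Tnni1 and 1 for Tmco5b in replicate 1. In PND1 controls it was 0.989 for Sohlh1, 0.848 for Uchl1 and 1 for Obox5 in replicate 1, 0.931 for Zar1l in replicate 2 and 1 for Serpina1c and Serpina6 in replicate 3. The ratios of 1 rest on 0.0739 to 0.222 CPM in 1 library and 0 in the others of its group, where any read gives 1. In PND1 cKO ovaries it was 0.921 for Gng13 and 0.87 for Cyp26b1 in replicate 1, 0.943 for Epcam and 0.892 for Gas1 in replicate 2, and 0.961 for Tmprss13 and 0.912 for Maf in replicate 3. At PND4 it was 0.842 for Serpina3n in control replicate 3, 0.832 for Corin in cKO replicate 1 and 0.835 for Irx3 in cKO replicate 4.

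The genotype effect differed between ED17.5 and PND1 for 325 genes in the test of the difference itself. Genes with a more positive effect at PND1 were Angptl7 (2.03), Lgr6 (2.32), Grik1 (2.64), Corin (1.39), Diras2 (1.95), Gbp2b (1.53), Chodl (2.62) and Cyp2f2 (1.65, from -2.62 to -0.97). The stromal genes Pdgfrb (0.98), Maf (0.66) and Col3a1 (0.63), the endothelial gene Pecam1 (0.66), the BMP genes Bmp2 (0.74, from -1.32 to -0.58) and Id3 (0.88), and the apoptosis gene Bmf (0.65) moved the same way. A more negative effect at PND1 was found for Rasal1 (-1.78), Rarres1 (-1.67), Rasl10a (-3.02), the glial gene Gfap (-2.46), the meiotic gene Prdm9 (-1.17) and the mitotic gene Bub1 (-0.39). The genes of granulocyte precursors Mpo (8.53), Ctsg (8) and Prtn3 (4.83) varied within groups: Mpo ranged from 3.74 to 174 CPM in ED17.5 controls and from 3.43 to 120 CPM in PND1 cKO ovaries. Of 16 leave-outs, 13 ended the call of Col3a1, 10 those of Prtn3 and Gfap, 8 that of Mpo and 3 that of Ctsg. The count was 216 without ED17.5 control replicate 3, 530 and 196 without ED17.5 cKO replicates 1 and 4, 216 and 205 without PND1 control replicates 1 and 2, and 157 without PND1 cKO replicate 3.

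For the difference between PND1 and PND4, 1003 of 17435 genes had an unadjusted edgeR p under 0.05. Chance alone gives a share of 0.05. The genotype effect differed for 18 genes by edgeR and 64 by DESeq2, both after adjustment. It was more positive at PND4 for Oprk1 (3.86, from -4.66 to -0.8, with both genotypes at a few counts at PND4, 0.435 CPM in controls and 0.243 in cKO ovaries, after 3.32 in PND1 controls), Trim66 (1.65), Astn1 (1.16), Thbs2 (0.95), Bace2 (0.9) and Id3 (0.43), and more negative for Grhl3 (-1.77), Pitpnm3 (-1.68), Tnni1 (-1.39), Sntb1 (-1.07), Plekha6 (-1.03) and Ccnd1 (-0.82). Of 16 leave-outs, 10 ended the calls of Astn1, Sntb1 and Id3, 8 that of Oprk1, 2 that of Trim66 and 1 that of Ccnd1. The count was 11 without PND1 control replicate 3, 10 without PND1 cKO replicate 4 and 49 without PND4 control replicate 5.

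Other splits of the same libraries were set against the real one. Of the 35 splits of each age, 1, the real one, gave as many genes as cKO against control: 4040 at ED17.5 (highest other 488, which exchanges replicate 3 of both genotypes), 4176 at PND1 (4) and 3999 at PND4 (399). The same held for age in controls, 1 of 35 each, with 9246 (8) and 5565 (203). With 35 splits no share under 1 of 35 is possible, and splits that mix the groups widen the spread within them. The real split thus stood first in each of these comparisons, which alone does not exclude chance. For the differences between ages, 7 of 100 splits gave at least 325 genes (highest other 4675) and 11 of 100 at least 18 (highest other 3828), but these splits decide nothing about chance. Each other split that reached the real count exchanges unequal numbers of labels at the 2 ages, so that the genotype effect itself enters the difference, which is a structure of the samples. Among the 37 splits with equal exchanges, 1, the real one, gave as many genes (highest other 40 and 0), yet exchanged labels also widen the spread within groups there, so whether chance accounts for these 2 counts stays open.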

How the results depend on the processing

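The settings that leave out ED17.5 cKO replicates 1 and 3 together, which hold the most Y-linked reads, or 4 ED17.5 libraries by number, and the estimated correlation without ED17.5 cKO replicate 3, were chosen after seeing the data. Of 280 gene results, 229 kept their direction and side of the threshold under every setting in which they could be computed and 51 changed under at least 1, of which 7 changed with leave-one-out alone. Calls were lost for 1 gene with DESeq2 size factors (largest median shift 0.0264), 14 with no filter (35897 genes tested), 20 with the 8 libraries of an age alone, 22 of 242 with a replicate block, 8 with library number sets as a block and 0 of 273 with DESeq2. The call of Nr5a1 at ED17.5 ended with no filter (adjusted p = 0.0761), with 8 libraries alone (0.231) and with a replicate block (0.0697) in edgeR, over a range up to 0.231. Of 87 list results, 48 kept theirs and 39 changed, 21 of which lost the call with an estimated correlation. Calls of lists were also gained, 6 with no filter (0 lost) and 6 with the 8 libraries of an age alone (1 lost). A replicate block gained 6 (2 lost) and DESeq2 gained 2 (1 lost). Some lists given as not passing thus pass under another setting. The counts of genes between genotypes stayed within 1.5 times under each setting: leaving out 1 library gave 3157 to 4168 at ED17.5, 3480 to 3949 at PND1 and 3118 to 4235 at PND4. The genes called changed more than the counts. At ED17.5 the fewest called again in the same direction were 2607 of 4040, without the 4 libraries numbered 13 to 24. At PND1 they were 3388 of 4176, without control replicate 1, and at PND4 2867 of 3999, with a replicate block. Which direction held more genes turned at each age under at least 1 of DESeq2 size factors, DESeq2 (2131 higher and 2019 lower at ED17.5, 2065 and 2156 at PND4) and no filter. The difference between ED17.5 and PND1 (325) was 608 with DESeq2, 658 without ED17.5 cKO replicates 1 and 3, and 157 (without PND1 cKO replicate 3) to 530 (without ED17.5 cKO replicate 1) with 1 library left out. That between PND1 and PND4 (18) was 64 with DESeq2, 64 with a replicate block, and 10 (without PND1 cKO replicate 4) to 49 (without PND4 control replicate 5). The cause was not tested. The replicate block was not run for age in controls, since each block lies within 1 age and the change between ages cannot be estimated beside it. PND4 control replicate 5 and PND4 cKO replicate 1 share their number with no library of the other genotype. Within blocks, the PND4 genotype effect is thus estimated without them. Directions reversed at ED17.5 without cKO replicate 3, without cKO replicates 1 and 3 and without the 4 libraries numbered 13 to 24, in this order: Cst9 -1.65, -1.7 and -1.74 (leave-one-out -1.65 to 3.68), Cyp17a1 -1.84, -1.83 and -1.78 (to 5.79), Cyp11a1 -0.76, -0.49 and -0.45 (to 5.1) and Amh -0.14, -0.65 and -0.98 (to 6.77). Dmrt1 was at -0.11 without the 4 libraries. Each of these 3 settings removes cKO replicate 3, which held these transcripts. In simulated data at this depth, 70% of planted 1.5-fold changes were called between genotypes, and 36% of those planted in the difference of the genotype effect between ages. These shares come from few planted genes, without those of lowest mean count, so they do not give the sensitivity in the data.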

Other observations

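Chosen after results were seen were the tests of the cell type pattern and, in the late-oocyte pattern, the tests of each share on the other set of genes (ratios 2.62 and 2.76); the other tests below were written down before their results were seen.

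Single genes of further lists also differed by genotype; the adhesion and basement membrane list gave adjusted p = 0.879, 0.0897 and 0.453 at ED17.5, PND1 and PND4. Epcam, an epithelial adhesion gene, fell at each age, by 0.9 ± 0.14, 0.97 ± 0.13 and 1.12 ± 0.13, as did Krt19, by 0.62 ± 0.18, 0.92 ± 0.18 and 1 ± 0.18 (at ED17.5 adjusted p = 0.018, and 0.0622 without cKO replicate 3, 0.0595 without control replicate 2 and 0.0527 without control replicate 3). Lama1, a laminin gene, fell by 1.11, 0.78 and 0.6, and Itga6, a laminin receptor gene, by 0.81 at ED17.5 and 0.51 at PND1, while Nid2, a nidogen gene, rose by 0.88, 1.45 and 0.97. Pax8, a transcription factor gene of duct epithelia, rose by 1.09 at PND1 and 1 at PND4. Tnni1, a slow troponin gene, fell by 1.47, 1.23 and 2.62, and Prph, a gene of peripheral neurons, rose by 1.73 at PND1 and 1.45 at PND4. Each adjusted p is from edgeR, with 4 libraries per group.

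Blood and liver transcripts varied between libraries of the same group. Hbb-bs, a hemoglobin gene with close paralogs, ranged from 1650 to 6380 CPM at ED17.5 and from 123 to 2630 CPM later. Alb and Afp ranged from 225 to 1240 and from 105 to 702 CPM in ED17.5 libraries and reached at most 15.1 and 7.51 CPM later. These genes were chosen after their values were seen.

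The 4 ED17.5 libraries numbered 13 to 24 held more transcripts of later oocytes than the 4 numbered 1 to 12, in both genotypes: Zp2 28.6 against 2.36, Zp3 9.13 against 0.179 and Padi6 38.6 against 1.32 CPM, with 13 genes higher and 0 lower by edgeR (1357 of 17435 at an unadjusted p under 0.05). By chance 0.05 of unchanged genes would pass the unadjusted threshold. With a 1.86% share of PND4 RNA or reads, the observed excess was a median of 0.698 of the predicted one (0.559 to 0.895 over libraries) over 8 genes neither used to set the share nor among those 13, and with a 6.68% share of tissue at the PND1 stage 0.592 (-0.251 to 0.704) over 67 genes. With the PND1 share these 8 genes, chosen by level and not by cell type, lay at 2.62 times the predicted excess (2.71 to 4.11 over libraries, each with a share of its own), but the share rests on an assumed profile and the set leaves out called genes, so this excludes nothing. For genes highest at PND1, a PND4 share leaves a ratio of 2.76 with a range of -1.42 to 3.67 over libraries, too wide to decide. A carried-over share of later RNA may account for part of the pattern, and a difference in stage between litters stays open.

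Pregranulosa markers were lower and stromal, vessel and macrophage markers higher in cKO ovaries, which may reflect cell numbers or expression per cell. If fewer pregranulosa cells gave all others a larger share, germ cell and stromal genes would rise alike, but the germ cell shift lay 1.39 below the stromal shift at PND1 (-1.39, SE 0.16, exact permutation p = 0.0286). If added stroma diluted all others, germ cell and pregranulosa genes would fall alike. PND1, the age named for that test, gave a germ cell shift 0.63 above the pregranulosa shift (SE 0.21, exact permutation p = 0.0571), and the other ages, taken up after PND1 had missed the threshold, 0.73 ± 0.18 at ED17.5 and 0.75 ± 0.13 at PND4 (exact permutation p = 0.0286 each). Each test takes a single change of cell numbers. Changes in the numbers of several cell types at once were not tested and stay open. So does a combination of dilution with lower transcription of pregranulosa genes in cells that lost SF-1.

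A hypothesis of a delayed course in cKO ovaries was tested by setting the change with age in controls against the genotype effect in libraries of another age. Over the 9246 genes that changed from ED17.5 to PND1 the correlation with the effect at PND4 was -0.316 (Spearman -0.421), a sign that a delay or a larger stromal share may give: all 13 theca and stroma genes fell with age and 10 rose in PND4 cKO ovaries. A delay of oocytes would lower the genes that rose with age, 20 of 21 of growing oocytes and 7 of 8 oocyte transcription factors. At PND4 0 of 21 and 0 of 8 passed (medians -0.121 and -0.083). For the genes of these lists, this argues against a large delay at PND4 and leaves a small one open. At ED17.5, whose controls also set the change with age, their medians were -0.446 and -0.481. Neither list passed there (camera adjusted p = 0.367 and 0.279). Meiotic prophase genes, most of which fell with age, had an ED17.5 median of 0.227 (0.0374, and 0.958 with an estimated correlation). A delay of oocytes at ED17.5, or of other cells, stays open. Over the 5565 genes that changed from PND1 to PND4 the correlation with the effect at ED17.5 was 0.217 (0.321), but libraries taken before that change cannot show whether it comes late, so this decides nothing. Genes are not independent replicates, so no p is given.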
